A study of Dinoroseobacter shibae with 24 samples.

How the data were processed

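Total RNA of Dinoroseobacter shibae wild type (WT) and of a transposon mutant in clpX (clpX::Tn) was measured on 24 arrays, 4 for each of the 6 combinations of strain (wild type, mutant) and light (light, blue light, dark). Per the labels' protocols, the cultures grew aerobically in shaken flasks of artificial seawater minimal medium to mid exponential phase, and the RNA was labelled with Cy3. The deposited values are spot intensity on the linear scale, extracted with Agilent Feature Extraction per the file headers, as the median brightness of each spot and of its local background. Neither column was normalized between arrays, per the file headers. A processed intensity column, corrected for background and for trends across the array by the same program per the file headers, served as an alternative. Limma is named in the submitters' processing notes with no role or version, and no normalized table was used here. The series is described as sequencing, while each file holds one array scan.

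Each array held 14999 spots and 12476 probes for 4102 gene identifiers, and 4007 genes had 3 probes of 45 to 60 bases. Of the probes, 204 were spotted 10 times, which made 2040 spots for 69 genes. The array names no genome build. Locus tags were matched to the supplied reference annotation for names, neighbours and replicons only, 3980 matched and 122 did not, and 34 probe sequences belonged to more than 1 gene. The gene symbols given for genes of 3 plasmids were shifted against the products of the same locus tags and were not used. Depth was judged by signal over background. The median signal per array was 204 to 1822.5, between 1.72 and 4.26 times the median of the negative controls, 40.6% to 78.4% of spots were well above background, and 0 spots were saturated.

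In the planned fit, background was corrected with normexp at an offset of 50, intensities were quantile normalized over all spots of all 24 arrays, control spots were removed, repeated spots averaged, and probes kept if they exceeded the 95th percentile of the negative controls by 10% on at least 4 arrays. This left 11686 probes and 4055 genes, whose values were means over probes. Linear models with a mean for each of the 6 groups were fitted with limma 3.58.1 in R 4.3.3 with trended and robust moderation. The 11 comparisons were the 3 light contrasts in each strain, the 3 strain contrasts and the 2 interactions of strain with light or blue light against dark. Tests were two-sided with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.

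The groups, comparisons, planned fit, alternatives and gene lists were fixed before the data were examined. After they were examined, 1 alternative averaged the repeated spots before quantile normalization, so that each probe counted once, another left out clpX::Tn dark replicate 2 and a further one did both. Median scaling with the median taken over probes, each counted once, was run for the shift of all genes only. Gene values are given from the first of these. In all, 36 gene lists and the 6 replicons were tested with camera at a preset correlation of 0.01, with adjustment over the 42 lists of a comparison, again with an estimated correlation, and with fry. Fry tests whether a list's genes move on balance one way and does not compare them with other genes. Membership was found by words in the product names and symbols, and 75 wrong word matches were dropped before any test.

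The genes to name were chosen by a rule. In the strain comparisons it took clpX, clpP, lon and the 3 genes on each side of clpX. In the 9 pairwise comparisons it took the 8 largest rises and the 8 largest falls among called genes with a known product and no overlap between the 4 arrays of each group. It took up to 4 called members of each list described, the 6 largest positive and negative interactions, and the largest riser and faller of each comparison. It was applied to the planned fit and to the fit that counts each probe once, and not every gene it allows is printed.

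The fits were tested on simulated data with 200 changed genes among 4066. For mutant minus wild type in the dark, 89% of the changed genes were called by either fit, 76.1% of those changed 1.5 times, 91.0% of those changed 2 times and 100% of those changed 4 times, and 6.81% (planned) or 5.82% (each probe once) of the calls were false. For the light interaction 75.5% and 74.5% were called. With no gene changed, 0 were called in wild type light minus dark. The simulated noise was independent between genes and alike on all arrays, with no slide effect and no poorly hybridized array. These rates may therefore not carry over to the real arrays. A separate simulation changed only the 69 genes with repeated probes. There the planned normalization called 2338 unchanged genes in wild type light minus dark, all of them up, and counting each probe once called 8.

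The alternatives were the processed intensity, no background correction, an offset of 1, cyclic loess, median scaling, no probe filter, the median over probes, moderation without trend and robustness, a replicate block, array weights, only the arrays compared, and each array left out in turn. No array was left out of the planned fit. A slide term was not fitted, because each light condition had its own slide, and strain went with the slide row.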

Results

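RNA from Dinoroseobacter shibae, a marine bacterium that makes bacteriochlorophyll and lives aerobically, was hybridized to 24 one-colour arrays. The wild type (labelled WT) and a mutant with a transposon in clpX (labelled clpX::Tn) were each grown in light, in blue light and in the dark, with 4 replicates in each of the 6 groups. The gene clpX encodes the unfoldase subunit of the ClpXP protease. On 23 arrays the median spot signal was 2.62 to 4.26 times that of the negative control spots, and 61.0% to 78.4% of spots lay well above background. On the other array, clpX::Tn dark replicate 2, these values were 1.72 and 40.6%, and its mean correlation with the other arrays of its group was 0.802 against 0.910 to 0.995 elsewhere. Each light condition was run on its own slide with both strains on every slide. A light effect within a strain therefore includes any slide effect, while the difference between the strains' light effects cancels an additive one. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

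Each comparison has 3 counts of genes. The first comes from the planned fit, which was normalized over all spots, the second from a fit in which every probe was counted once, and the third from that same fit without clpX::Tn dark replicate 2. The latter 2 fits were chosen after the data were seen, because 204 probes spotted 10 times each made up 14.3% of the gene spots. The choice of scaling moved the median log2 change of all genes. In the planned fit it was 0.34 for wild type in light minus dark, 0.33 for wild type in blue light minus dark, 0.25 for mutant minus wild type in the dark and -0.27 for each interaction. With each probe counted once these medians were 0.05, 0.05, 0.05, -0.06 and -0.05, and with median scaling 0.30, 0.28, 0.24, -0.24 and -0.21. In the other comparisons every scaling left them within 0.1 of 0. Values for genes and gene lists are from the fit that counts each probe once, as log2 fold change ± SE with n = 4 arrays per group. Every gene named as having risen or fallen passed in both that fit and the planned one, with all 4 arrays of one group above all 4 of the other unless stated.

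The targeted gene came first, as a check of the strain labels. The log2 intensity of clpX (Dshi_1387) lay between 12.40 and 12.77 on the 12 wild type arrays and between 10.92 and 11.14 on the 12 mutant arrays. The change was -1.47 ± 0.08 in the dark (adjusted p = 1.69e-12), -1.63 ± 0.08 in light (adjusted p = 4.65e-13) and -1.58 ± 0.08 in blue light (adjusted p = 5.02e-13). The 3 probes of clpX did not move alike. In light they differed by -3.41, -1.65 and 0.17, and the labels do not place the transposon, so the gene's mean can understate the loss of transcript. The third probe was not lower in blue light (0.28) or in the dark (0.78) either. Loss of ClpX function was not measured. The neighbouring clpP (Dshi_1388), the proteolytic subunit of the same protease, was not called in the dark (0.33 ± 0.21, adjusted p = 0.234), in light (0.46 ± 0.21, adjusted p = 0.134) or in blue light (0.36 ± 0.21, adjusted p = 0.255). The gene lon (Dshi_1777), which encodes another ATP-dependent protease, had values of 0.23 ± 0.23, 0.39 ± 0.23 and 0.44 ± 0.23 (adjusted p = 0.432, 0.257 and 0.183). Without clpX::Tn dark replicate 2 both genes were called in all 3 conditions, with 0.71 and 0.58 in the dark. The adjusted p was then 1.03e-10, 2.79e-08 and 1.16e-06 for clpP and 0.00333, 0.0271 and 0.0125 for lon. Each gene's spread was estimated over all 6 groups, so this array also entered the SE in light and blue light. The changes there stayed at 0.46 and 0.36 for clpP and at 0.39 and 0.44 for lon without it. The planned fit called both in the dark (0.78 and 0.67), but cyclic loess (adjusted p = 0.408 and 0.73), median scaling (0.181 and 0.39) and only the arrays compared (0.118 and 0.155) did not. In that fit lon lost its call with the median over probes (0.122) and without wild type dark replicate 1 (0.0564), clpX::Tn dark replicate 1 (0.0784) or 3 (0.1). In light, clpP gained a call with the processed intensity (adjusted p = 0.0144), the median over probes (0.0151), array weights (2.18e-08) and only the arrays compared (6.66e-05). In blue light, clpP and lon gained one with the processed intensity (0.0196 and 0.0187), array weights (4.72e-08 and 3.68e-05) and only the arrays compared (0.00025 and 7.58e-05).

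The comparison of wild type in light with wild type in the dark asked which genes responded to light. The photosynthesis genes were far lower in light. The antenna genes pufA (Dshi_3522) and pufB (Dshi_2900) changed by -7.36 ± 0.13 (adjusted p = 3.68e-22) and -7.12 ± 0.07 (adjusted p = 3.03e-26). The reaction centre gene pufM (Dshi_3524) changed by -5.12 ± 0.08. Mean log2 intensity of pufA was 8.97 ± 0.05 (SD, n = 4) in light and 16.33 ± 0.06 in the dark. All 15 measured photosystem and light harvesting genes fell, with a median of -5.03. So did all 19 bacteriochlorophyll biosynthesis genes, with a median of -2.99, and all 7 carotenoid genes, with a median of -3.09. Adjusted over the list alone the counts were the same. The lists passed camera with adjusted p = 5.15e-84, 5.42e-79 and 1.52e-28, or 5.45e-10, 8.65e-07 and 0.00038 with an estimated correlation. Examples were bchY (Dshi_3518) and bchX (Dshi_3517), subunits of the reductase that turns chlorophyllide towards bacteriochlorophyll, at -6.83 ± 0.09 and -5.46 ± 0.12, and crtE (Dshi_3514), which makes the carotenoid precursor geranylgeranyl diphosphate, at -3.68 ± 0.13. The hemA gene (Dshi_3546), which encodes the first enzyme of tetrapyrrole synthesis, changed by -5.47 ± 0.07. The regulators ppaA (Dshi_3532) and ppsR (Dshi_3531), the latter a repressor of photosynthesis genes, changed by -2.49 ± 0.08 and -1.13 ± 0.06, the 2 of 10 genes of photoreceptors and photosynthesis regulators that passed (3 fell adjusted over the list alone, and 4 without clpX::Tn dark replicate 2). That list passed camera (adjusted p = 0.000308, and 0.00421 with an estimated correlation) with a median of -0.22 that was 0.09 in the planned fit. In the light arrays only 65.5% of the photosystem, 42.1% of the bacteriochlorophyll and 41.1% of the carotenoid probes exceeded the limit set by the negative controls, against 100% of each in the dark, so background limits what these folds measure.

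Among the genes that rose in light in the wild type were many of respiration. The largest riser was Dshi_1299, an OmpW family outer membrane protein (4.27 ± 0.25, adjusted p = 4.7e-12), and the TraR/DksA family regulator Dshi_1411 rose as well (3.29 ± 0.17, adjusted p = 3.87e-13). The catalytic subunit gene ccoN (Dshi_0661) of the high-affinity cbb3 oxidase rose by 2.89 ± 0.21, and ccoO (Dshi_0662) by 3.20 ± 0.24. Rises were also found for hemN (Dshi_0541), an oxygen-independent heme synthesis enzyme, at 2.94 ± 0.14, and for the CRP/FNR type regulator dnrF (Dshi_3270) at 2.84 ± 0.15. Of 21 genes of cytochrome oxidases and the bc1 complex, 9 rose, 2 fell and 10 did not pass (median 0.47, camera adjusted p = 0.00398, adjusted p = 0.01 with an estimated correlation but 0.1 without clpX::Tn dark replicate 2, where 11 rose and 4 fell). Of 20 NADH dehydrogenase genes, 15 rose and 1 fell, or 16 and 1 adjusted over the list alone (median 0.54, adjusted p = 4.23e-07, and 0.00478 with an estimated correlation). One of them was nuoC (Dshi_1309) at 0.88 ± 0.11. Of 17 TCA cycle genes 9 rose and none fell, also adjusted over the list alone (median 0.56, adjusted p = 5.48e-06, and 0.000445 with an estimated correlation). Examples were sucC (Dshi_2878) at 0.94 ± 0.09 and icd (Dshi_1986) at 0.81 ± 0.08. Of 38 denitrification genes 12 rose, 14 adjusted over the list alone (median 0.23, adjusted p = 8.19e-06, but adjusted p = 0.0649 with an estimated correlation, and 0.00333 without clpX::Tn dark replicate 2). These included all 7 genes of the periplasmic nitrate reductase (median 1.44), with napA (Dshi_3165) at 2.49 ± 0.13, while 2 of the 18 genes for the later steps (nir, nor and nos) rose. The planned fit called 2424 of 4055 genes, 2353 up and 71 down. With each probe counted once there were 429 (325 up, 104 down), and with cyclic loess 375 (254 up, 121 down). Leaving out clpX::Tn dark replicate 2 brought the former to 922 (712 up, 210 down).

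**Figure D1:**
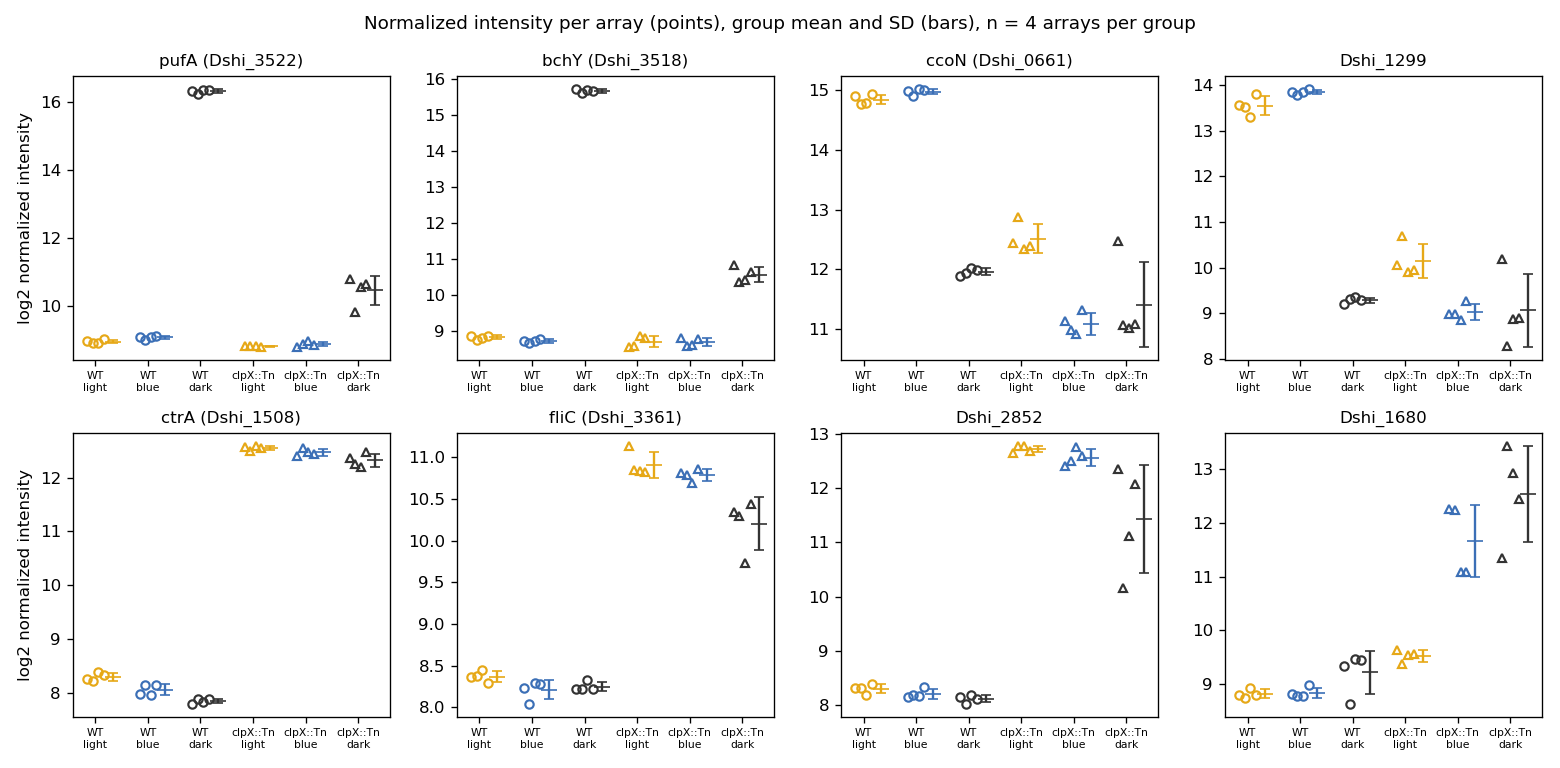
Log2 normalized intensity (vertical axis) of 8 genes on each array, by strain and light condition (horizontal axis), with each probe counted once. Points are arrays (circles wild type, triangles mutant) and bars are the mean and SD of 4 arrays. The gene pufA sat at 16.33 in wild type in the dark and at 10.47 in the mutant in the dark, and ctrA at 8.30 in wild type and 12.55 in the mutant in light.

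Wild type in blue light against wild type in the dark asked the same of blue light. It shares its 4 dark arrays with the comparison above, so part of any likeness between them may come from those arrays. The gene pufA changed by -7.24 ± 0.13 (adjusted p = 4.55e-22), bchY by -6.93 ± 0.09 and hemA by -5.52 ± 0.07. All 15 photosystem genes (median -5.04), all 19 bacteriochlorophyll genes (median -3.02) and all 7 carotenoid genes (median -2.92) fell, with adjusted p = 5.85e-71, 1.06e-65 and 1.67e-24, or 2.37e-09, 3.56e-06 and 0.0007 with an estimated correlation. Adjusted over the list alone the counts were equal. Dshi_1299 rose by 4.57 ± 0.25, Dshi_1411 by 3.82 ± 0.17, hemN (Dshi_0541) by 3.48 ± 0.14, the universal stress gene uspA (Dshi_1338) by 3.28 ± 0.17, dnrF by 3.22 ± 0.15 and ccoO by 3.21 ± 0.24. NADH dehydrogenase had 16 of 20 genes up and 1 down (18 and 1 adjusted over the list alone, median 0.67, adjusted p = 2.52e-08, and 0.00259 with an estimated correlation). The TCA cycle had 8 of 17 up (also 8 adjusted over the list alone, 13 without clpX::Tn dark replicate 2, median 0.53, adjusted p = 1.37e-05, and 0.0007 with an estimated correlation). The cytochrome oxidase list had 9 of 21 genes up and 1 down (median 0.56, adjusted p = 0.00153, and 0.00537 with an estimated correlation but 0.0607 without clpX::Tn dark replicate 2, where 11 rose and 4 fell). Denitrification had 11 of 38 up (13 adjusted over the list alone, median 0.21, adjusted p = 4.17e-05, but adjusted p = 0.0865 with an estimated correlation, and 0.00542 without clpX::Tn dark replicate 2). All 7 nap genes were among them (median 1.46). Genes called in the planned fit numbered 2285, 2210 up and 75 down. With each probe counted once there were 553 (388 up, 165 down), and with cyclic loess 555 (345 up, 210 down). Leaving out clpX::Tn dark replicate 2 brought the former to 1175 (821 up, 354 down).

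Wild type in blue light against wild type in light compared the colours. Few genes differed, several of them annotated for sugar breakdown. The Entner-Doudoroff dehydratase gene edd (Dshi_1769) was higher by 2.52 ± 0.26 (adjusted p = 1.45e-05). The gene zwf (Dshi_1684), for the first enzyme of that route, was higher by 1.60 ± 0.18 and the pyruvate kinase gene pyk (Dshi_0228) by 1.31 ± 0.15 (both adjusted p = 2.32e-05). Smaller rises were those of the glucokinase gene glk (Dshi_1655), at 0.65 ± 0.09, and of serC (Dshi_3317), for an enzyme of serine synthesis, at 0.85 ± 0.11 (both adjusted p = 0.000111). The call of glk was lost with the median over probes (adjusted p = 0.0552) and that of serC with only the arrays compared (adjusted p = 0.05). The genes annotated as gap moved in opposite directions, Dshi_1742 by 1.87 ± 0.38 (adjusted p = 0.0186) and Dshi_1740 by -1.05 ± 0.20 (adjusted p = 0.0126). In the planned fit neither was called with an offset of 1 (adjusted p = 0.0847 and 0.068), without wild type light replicate 1 or 2, or without wild type blue replicate 1, 3 or 4 (adjusted p of 0.0825 to 0.132 and 0.0512 to 0.109). Dshi_1742 was not called without wild type light replicate 3 (0.0944) or with the median over probes (0.0552). No list fixed in advance held these sugar genes, and no list was called. With clpX::Tn dark replicate 2 left out, NADH dehydrogenase was called (adjusted p = 0.0217, but adjusted p = 0.595 with an estimated correlation). The median of the 15 photosystem genes was -0.02. The planned fit called 22 genes, 18 up and 4 down, and each probe counted once gave 20 (16 up, 4 down). The split was 14 up and 6 down with cyclic loess and 16 up and 1 down with median scaling. Single arrays decided this count. It was 9 without wild type light replicate 2 and 14, 12 and 10 without wild type blue replicates 1, 3 and 4. Without clpX::Tn dark replicate 2, an array outside the comparison, it was 108, and 105 (56 up, 49 down) when each probe was also counted once.

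In the mutant, light against dark asked whether the response to light remained in that strain. The photosynthesis genes fell again, by much less, but background limits how large a fall could be measured. In the mutant in the dark 85.4% of the photosystem, 74.5% of the bacteriochlorophyll and 67.3% of the carotenoid probes exceeded the limit set by the negative controls. The shares in light were 68.5%, 46.9% and 45.2%. The gene bchY changed by -1.86 ± 0.09 (adjusted p = 3.67e-12), pufA by -1.64 ± 0.13 (adjusted p = 5.49e-09) and puhA (Dshi_3540), a reaction centre subunit gene, by -1.26 ± 0.06 (adjusted p = 4.69e-12). All 15 photosystem genes fell (median -0.70, camera adjusted p = 6.84e-23, and 1.84e-05 with an estimated correlation). So did 16 of 19 bacteriochlorophyll genes (median -0.65, adjusted p = 2.28e-20, and 0.00604 with an estimated correlation). Of 7 carotenoid genes 5 fell (median -0.32, adjusted p = 0.00182, but adjusted p = 0.332 with an estimated correlation). These counts were equal adjusted over the list alone, and 3 carotenoid genes fell without clpX::Tn dark replicate 2. The largest falls lay outside photosynthesis, several of them in genes annotated for methyl group transfer. Among them were those of the periplasmic binding protein gene Dshi_0561 (-3.02 ± 0.26), the ferredoxin gene Dshi_1680 (-3.01 ± 0.32), and the MetF-like Dshi_1675 (-2.65 ± 0.26). Others were bmt (Dshi_1074), annotated as methionine synthase (-2.44 ± 0.26), metF (Dshi_2080), which makes methyltetrahydrofolate (-2.31 ± 0.23), and cobW (Dshi_0160), a gene of cobalamin metabolism (-2.03 ± 0.23). They were set side by side after their values were seen, not as a list fixed in advance.

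Flagellar genes were higher in the mutant in light than in the dark. Of 31 flagellum genes 24 rose, also 24 adjusted over the list alone (median 0.59, adjusted p = 8.62e-16, and 0.0269 with an estimated correlation). The hook gene flgE (Dshi_3379) rose by 1.21 ± 0.23 and the ring gene flgH (Dshi_3254) by 0.96 ± 0.14. Phosphate uptake had 2 of 12 genes up, 7 adjusted over the list alone (median 0.27, adjusted p = 0.00603, and 0.0289 with an estimated correlation but 0.0676 without clpX::Tn dark replicate 2). In denitrification 1 of 38 genes rose and 5 fell (median -0.19, adjusted p = 0.0233, but adjusted p = 0.376 with an estimated correlation). In iron uptake and storage 1 of 18 rose and 4 fell (median -0.23, adjusted p = 0.0135, but adjusted p = 0.332 with an estimated correlation). The 53 ribosomal protein genes had a median of 0.40 with 6 up (adjusted p = 1.83e-05, but adjusted p = 0.457 with an estimated correlation and 0 called adjusted over the list alone). With clpX::Tn dark replicate 2 left out, camera called NADH dehydrogenase (8 of 20 down, median -0.21, adjusted p = 3.24e-05, and 0.0411 with an estimated correlation) and heme biosynthesis (2 of 13 up, 6 down, median -0.26, adjusted p = 0.000887, and 0.0138 with an estimated correlation), which did not pass with it (adjusted p = 0.108 and 0.141). In that fit 6 phosphate uptake genes rose, 2 denitrification genes rose and 8 fell, and the medians of denitrification, iron uptake and ribosomal proteins were -0.04, -0.10 and 0.18. Genes called in the planned fit numbered 870, 585 up and 285 down. Counting each probe once gave 701 (364 up, 337 down), and cyclic loess gave 507 (277 up, 230 down). Each probe counted once without clpX::Tn dark replicate 2 gave 675 (360 up, 315 down). With only the 8 compared arrays normalized and fitted, 38 genes were called (5 up, 33 down), and flgE and flgH were not among them. Leaving out clpX::Tn light replicates 1 to 4 in turn gave 536, 573, 474 and 502 genes, and leaving out clpX::Tn dark replicate 1 gave 1503.

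Blue light against dark in the mutant asked the same for blue light. The photosynthesis genes fell here as well, against the same 4 dark arrays, while none of the 6 genes from Dshi_1675 to Dshi_1680 was called (median -0.29). In blue light 76.8% of the photosystem, 56.0% of the bacteriochlorophyll and 48.8% of the carotenoid probes exceeded the limit set by the negative controls. Background limits the size of these falls too. The gene bchY changed by -1.87 ± 0.09 and puhA by -1.32 ± 0.06 (both adjusted p = 1.73e-12), pufA by -1.58 ± 0.13 (adjusted p = 9.74e-09) and hemA by -1.22 ± 0.07. All 15 photosystem genes fell (median -0.85, adjusted p = 2.56e-27, and 5.11e-06 with an estimated correlation). Of 19 bacteriochlorophyll genes 17 fell, 18 adjusted over the list alone (median -0.70, adjusted p = 1.28e-24, and 0.00222 with an estimated correlation). The same held for 6 of 7 carotenoid genes, 7 adjusted over the list alone (median -0.55, adjusted p = 2.14e-06, but adjusted p = 0.152 with an estimated correlation, and 0.0236 without clpX::Tn dark replicate 2). In the denitrification list 9 of 38 genes fell, 10 adjusted over the list alone (median -0.25, adjusted p = 0.000184, but adjusted p = 0.152 with an estimated correlation). Leaving out clpX::Tn dark replicate 2 brought that median to -0.03 and the latter p to 0.0111. Of these, 5 were nap genes, with napD (Dshi_3166) at -0.94 ± 0.13. Of 31 flagellum genes 16 rose, while adjusted over the list alone 19 rose and 1 fell (median 0.34, adjusted p = 1e-07, but adjusted p = 0.152 with an estimated correlation). The gene flaF (Dshi_3360), a regulator of flagellin synthesis, rose by 0.85 ± 0.14. Of 13 heme biosynthesis genes 4 fell, hemA among them, and 5 adjusted over the list alone (median -0.18, adjusted p = 0.00674, and 0.0438 with an estimated correlation). Genes called in the planned fit numbered 700, 508 up and 192 down. Counting each probe once gave 510 (253 up, 257 down), and cyclic loess gave 204 (78 up, 126 down). Each probe counted once without clpX::Tn dark replicate 2 gave 444 (256 up, 188 down). With only the compared arrays 25 genes were called, 0 up and 25 down, and flaF was not among them. The count was 332, 270 and 378 without clpX::Tn blue replicates 2, 3 and 4, and 1412 without clpX::Tn dark replicate 1.

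Blue light against light in the mutant compared the colours in that strain. Several of the genes that fell in light were higher in blue light, measured against the same 4 light arrays, with Dshi_0561 at 2.50 ± 0.26 (adjusted p = 6.29e-06), Dshi_1680 at 2.14 ± 0.32 (adjusted p = 0.000293), Dshi_1675 at 2.08 ± 0.26 (adjusted p = 3.92e-05) and metF at 2.08 ± 0.23 (adjusted p = 9.71e-06). The cbb3 oxidase genes were lower, ccoN at -1.43 ± 0.21 (adjusted p = 0.000293) and ccoO at -1.24 ± 0.24 (adjusted p = 0.00425, but 0.071 with the median over probes), together with hemN (Dshi_0659) at -1.28 ± 0.12 (adjusted p = 6.14e-07). Of 20 NADH dehydrogenase genes 3 rose, 5 adjusted over the list alone (median 0.24, camera adjusted p = 5.68e-08, and 0.0134 with an estimated correlation), with nuoN (Dshi_1329) at 0.41 ± 0.08 (not called with median scaling, adjusted p = 0.43). Of 17 TCA cycle genes 4 rose, 5 adjusted over the list alone (median 0.16, adjusted p = 0.0141, but adjusted p = 0.054 with an estimated correlation). The flagellum list had a median of -0.23 and passed camera (adjusted p = 8.04e-09, but adjusted p = 0.181 with an estimated correlation), while 0 of its 31 genes were called and 5 were lower adjusted over the list alone. With clpX::Tn dark replicate 2 left out there were 9 NADH dehydrogenase and 7 TCA cycle genes up and 6 flagellum genes down, and adjusted p = 0.241 with an estimated correlation for the TCA cycle. The planned fit called 81 genes, 43 up and 38 down. Counting each probe once gave 88 (43 up, 45 down), and leaving out clpX::Tn dark replicate 2 as well gave 286 (144 up, 142 down). The planned count was 52 without clpX::Tn light replicate 3 and 45 and 53 without clpX::Tn blue replicates 2 and 3. It was 277 without clpX::Tn dark replicate 2, which lies outside the comparison, and 707 with only the compared arrays.

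Mutant against wild type in the dark asked what differed between the strains where wild type photosynthesis genes are high. These genes were far lower in the mutant. The antenna genes Dshi_2899 and pufB (Dshi_2900) changed by -6.24 ± 0.12 (adjusted p = 4.11e-21) and -6.14 ± 0.07 (adjusted p = 7.07e-25), pufA by -5.86 ± 0.13 (adjusted p = 3.03e-20), bchY by -5.09 ± 0.09 (adjusted p = 4.9e-22) and hemA by -4.27 ± 0.07. All 15 photosystem genes (median -4.40), all 19 bacteriochlorophyll genes (median -2.40) and all 7 carotenoid genes (median -2.66) fell, also adjusted over the list alone. Their lists had adjusted p = 1.57e-38, 1.06e-34 and 2.08e-13, or 3.69e-07, 0.000294 and 0.0102 with an estimated correlation. The gene ctrA (Dshi_1508), the response regulator that governs flagella and the cell cycle in many Alphaproteobacteria, rose by 4.47 ± 0.07 (adjusted p = 7.08e-23). The LuxR family regulator Dshi_2852 rose by 3.32 ± 0.27 and the diguanylate cyclase gene Dshi_2820, whose product makes cyclic di-GMP, by 2.34 ± 0.09. Rises were also found for the autoinducer synthase gene luxI (Dshi_0312), at 1.91 ± 0.06, and for sciP (Dshi_1507), an inhibitor of CtrA, at 1.34 ± 0.12. Of 31 flagellum genes 29 rose, 30 adjusted over the list alone (median 1.14, adjusted p = 1.62e-19, and 0.00791 with an estimated correlation). The flagellin gene fliC (Dshi_3361) rose by 1.96 ± 0.11 and flgE by 1.96 ± 0.23. In wild type in the dark 41.4% of the flagellum probes exceeded the limit set by the negative controls, against 80.9% in the mutant. The log2 values of ctrA (7.80 to 7.89) and Dshi_2852 (8.02 to 8.18) there lay below those of fliC (8.22 to 8.32). Background may therefore limit these folds. All 4 cyclic di-GMP genes rose (median 0.67, adjusted p = 0.00288, and 0.0161 with an estimated correlation). The list of quorum sensing and LuxR regulators, which holds luxI and Dshi_2852, went both ways and was not called in the dark (7 of 17 up, 3 down, adjusted p = 0.208), in light (5 up, 5 down, adjusted p = 0.729) or in blue light (5 up, 5 down, adjusted p = 0.494), and 5 fell in the dark without clpX::Tn dark replicate 2. Of 4 cell cycle regulators 2 rose (median 0.74, adjusted p = 0.0135, but adjusted p = 0.0534 with an estimated correlation, and 3 genes at 0.0195 without clpX::Tn dark replicate 2).

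Further groups differed between the strains in the dark. The Dshi_1675 to Dshi_1680 block had 5 of 6 genes up and 1 down, with Dshi_1680 at 3.32 ± 0.32 and Dshi_1675 at 2.72 ± 0.26. The heat shock sigma factor gene rpoH (Dshi_2609) rose by 1.76 ± 0.21 while rpoH2 (Dshi_2978), another sigma factor of that family, changed by -2.53 ± 0.14. Of 12 phosphate uptake genes 8 fell, also adjusted over the list alone (median -0.42, adjusted p = 0.00146, and 0.0102 with an estimated correlation). NADH dehydrogenase had 10 of 20 genes up and 1 down (11 and 1 adjusted over the list alone, median 0.35, adjusted p = 0.00766), and the TCA cycle had 8 of 17 up (9 adjusted over the list alone, median 0.27, adjusted p = 0.0445). Denitrification had 10 of 38 up and 1 down (median 0.20, adjusted p = 0.0323), and iron uptake and storage 7 of 18 up (9 adjusted over the list alone, median 0.45, adjusted p = 0.016). With an estimated correlation none of the 4 lists passed (adjusted p = 0.108, 0.0741, 0.347 and 0.267). With clpX::Tn dark replicate 2 left out there were 17 NADH dehydrogenase and 13 TCA cycle genes up (adjusted p = 0.0195 and 0.0403 with an estimated correlation), a denitrification median of 0.06 that did not pass (adjusted p = 0.187), and 49 genes of pDSHI05 down. All 7 nap genes rose (median 1.52), with napD at 1.80 ± 0.13. Of 53 genes on plasmid pDSHI04, 32 rose and 3 fell (35 and 3 adjusted over the list alone, median 0.39, adjusted p = 1.59e-06, and 0.000756 with an estimated correlation). On pDSHI05 31 of 70 genes fell, also adjusted over the list alone (median -0.35, adjusted p = 9.52e-09, but adjusted p = 0.319 with an estimated correlation, and 0.00333 without clpX::Tn dark replicate 2). Genes called in the planned fit numbered 2122, 1851 up and 271 down. Counting each probe once gave 1501 (922 up, 579 down), and cyclic loess gave 1248 (548 up, 700 down). Each probe counted once without clpX::Tn dark replicate 2 gave 1768 (1050 up, 718 down).

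**Figure D2:**
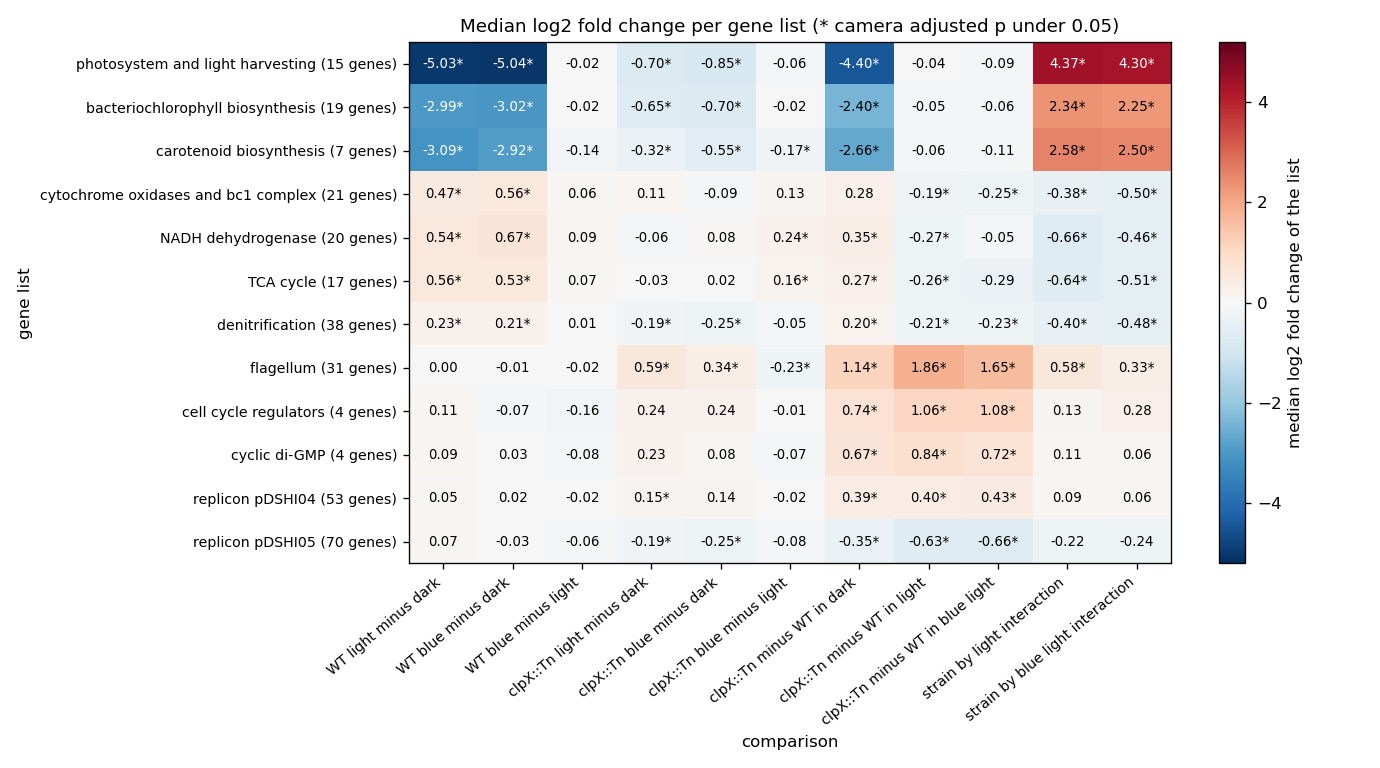
Median log2 fold change (colour and number) of 12 gene lists (vertical axis) in the 11 comparisons (horizontal axis), with each probe counted once, where an asterisk marks a camera adjusted p under 0.05. The photosystem list stood at -5.03 in wild type light minus dark and -0.70 in the mutant, no median with an asterisk changed sign under another scaling, and several without one did, the photosynthesis lists of mutant minus wild type in light and in blue light among them.

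Mutant against wild type in light asked the same question where photosynthesis genes are low in both strains. No photosystem gene was called here, and the list median was -0.04, but 4 of 15 were lower without clpX::Tn dark replicate 2. Only 65.5% of the photosystem probes in wild type and 68.5% in the mutant exceeded the limit set by the negative controls. Background may therefore hide a difference between the strains in these genes. Flagellar genes were higher in the mutant. Dshi_2852 rose by 4.43 ± 0.27 (adjusted p = 1.59e-11), ctrA by 4.25 ± 0.07 (adjusted p = 4.14e-22), flgE by 2.95 ± 0.23 (adjusted p = 9.23e-10) and fliC by 2.54 ± 0.11 (adjusted p = 4.1e-14). Others were the anti-sigma factor antagonist gene Dshi_0073 at 2.51 ± 0.10, Dshi_2820 at 2.44 ± 0.09, the motor gene motA (Dshi_3260) at 2.34 ± 0.14 and luxI at 1.87 ± 0.06. Of 31 flagellum genes 29 rose, 30 adjusted over the list alone (median 1.86, adjusted p = 1.18e-39, and 0.000303 with an estimated correlation). In wild type in light 37.9% of the flagellum probes exceeded the limit set by the negative controls against 97.3% in the mutant. Cell cycle regulators and cyclic di-GMP genes each had 3 of 4 up and 4 of 4 adjusted over the list alone (medians 1.06 and 0.84, adjusted p = 7.49e-05 and 0.000116, or 0.00407 and 0.00402 with an estimated correlation). The competence genes comF (Dshi_3500) and dprA (Dshi_1138), which serve DNA uptake, rose by 1.44 ± 0.08 and 1.42 ± 0.11. Of 19 genes for SOS response, repair and competence 8 rose and 2 fell (9 and 2 adjusted over the list alone, median 0.17, adjusted p = 0.00883, and 0.0236 with an estimated correlation).

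Among the genes lower in the mutant in light, Dshi_2673, annotated as binding pyrroloquinoline quinone, changed by -3.42 ± 0.16 (adjusted p = 2.38e-13), and Dshi_1299 by -3.40 ± 0.25. The cytochrome c genes Dshi_2672 and pedF (Dshi_2663) changed by -2.89 ± 0.26 and -2.72 ± 0.11, Dshi_1411 by -2.69 ± 0.17, ccoO by -2.55 ± 0.24, ccoN by -2.33 ± 0.21 and dnrF by -2.23 ± 0.15. In the cytochrome oxidase list 8 of 21 genes fell and 4 rose, 9 and 4 adjusted over the list alone (median -0.19, adjusted p = 0.0287, and 0.0479 with an estimated correlation, but not called without clpX::Tn dark replicate 2, at 0.0718). Of 17 TCA cycle genes 6 fell, also adjusted over the list alone (median -0.26, adjusted p = 0.0199, and 0.0395 with an estimated correlation), with sucC at -0.96 ± 0.09. NADH dehydrogenase had 7 of 20 down and 1 up (9 and 1 adjusted over the list alone, median -0.27, adjusted p = 0.0202, but adjusted p = 0.153 with an estimated correlation). Denitrification had 15 of 38 down, also adjusted over the list alone (median -0.21, adjusted p = 0.000469, but adjusted p = 0.128 with an estimated correlation). With clpX::Tn dark replicate 2 left out there were 10 TCA cycle and 13 NADH dehydrogenase genes down, with adjusted p = 0.0769 for the TCA cycle and 0.013 for denitrification with an estimated correlation. On pDSHI04 31 of 53 genes rose and 1 fell (38 and 1 adjusted over the list alone, median 0.40, adjusted p = 2.11e-13, and 1.43e-05 with an estimated correlation). On pDSHI05 43 of 70 fell, 51 adjusted over the list alone (median -0.63, adjusted p = 2.76e-16, but adjusted p = 0.138 with an estimated correlation, and 0.00371 without clpX::Tn dark replicate 2). The planned fit called 933 genes, 355 up and 578 down, and each probe counted once gave 946 (408 up, 538 down). Without clpX::Tn dark replicate 2, which lies outside the comparison, the counts were 1668 and 1677 (820 up, 857 down in the latter).

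Mutant against wild type in blue light asked this again in that light. Of the genes called, 736 were called in the same direction in light and in blue light, comparisons that share no arrays, against 126 for independent lists of those sizes. Both comparisons share their strains, the normalization and the estimate of each gene's spread, so their lists are not independent. In all 3 conditions 214 genes were higher and 193 lower. The gene ctrA rose by 4.40 ± 0.07 (adjusted p = 1.96e-22), Dshi_2852 by 4.37 ± 0.27 (adjusted p = 1.6e-11), flgE by 2.69 ± 0.23, fliC by 2.58 ± 0.11 and luxI by 2.16 ± 0.06 (adjusted p = 3.04e-17). Of 31 flagellum genes 29 rose, 30 adjusted over the list alone (median 1.65, adjusted p = 5.14e-32, and 0.00109 with an estimated correlation). So did 3 of 4 cell cycle regulators (median 1.08, adjusted p = 6.63e-05) and 4 of 4 cyclic di-GMP genes (median 0.72, adjusted p = 0.00024), both at 0.0048 with an estimated correlation. Dshi_1680 rose by 2.83 ± 0.32, metF by 2.73 ± 0.23 and Dshi_1675 by 2.62 ± 0.26. Dshi_1299 changed by -4.84 ± 0.25 (adjusted p = 5.56e-13), Dshi_1411 by -4.28 ± 0.17, ccoN by -3.90 ± 0.21 (adjusted p = 1.72e-12) and ccoO by -3.79 ± 0.24. Other falls were those of hemN (Dshi_0659) at -3.77 ± 0.12 (adjusted p = 1.07e-16), uspA at -3.77 ± 0.17 and the small heat shock protein gene Dshi_2796 at -3.09 ± 0.15. The cytochrome oxidase list had 8 of 21 genes down and 4 up, 9 and 4 adjusted over the list alone (median -0.25, adjusted p = 0.0259, and 0.0497 with an estimated correlation, but not called without clpX::Tn dark replicate 2, at 0.0885). Denitrification had 12 of 38 down, also adjusted over the list alone (median -0.23, adjusted p = 3.46e-05, but adjusted p = 0.0788 with an estimated correlation). The lists of NADH dehydrogenase (1 of 20 up, 3 down) and of the TCA cycle (1 of 17 up, 3 down) were not called (adjusted p = 0.568 and 0.249). Iron-sulfur cluster assembly had 5 of 10 up, 6 adjusted over the list alone (median 0.59, adjusted p = 0.00571, but adjusted p = 0.0831 with an estimated correlation). When clpX::Tn dark replicate 2 was left out, there were 4 NADH dehydrogenase genes up and 6 down, 3 TCA cycle genes up and 9 down, and 21 denitrification genes down, with adjusted p = 0.00348 with an estimated correlation, and 9 iron-sulfur genes up. The regulator gene iscR (Dshi_1633) rose by 0.90 ± 0.12. On pDSHI04 35 of 53 genes rose and 1 fell (median 0.43, adjusted p = 4.09e-11, and 5.45e-05 with an estimated correlation). On pDSHI05 45 of 70 fell, 48 adjusted over the list alone (median -0.66, adjusted p = 2.32e-16, but adjusted p = 0.137 with an estimated correlation, and 0.00348 without clpX::Tn dark replicate 2). The planned fit called 1054 genes, 491 up and 563 down, and each probe counted once gave 1083 (539 up, 544 down). Without clpX::Tn dark replicate 2, which lies outside the comparison, the counts were 1781 and 1797 (940 up, 857 down in the latter).

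The interaction of strain and light tested whether the change from dark to light differed between mutant and wild type, and positive values mean a higher change in the mutant. The largest differences were in photosynthesis genes, with Dshi_2899 at 6.32 ± 0.17 (adjusted p = 5.24e-18), pufB (Dshi_2900) at 6.11 ± 0.10 (adjusted p = 1.27e-21), pufA at 5.72 ± 0.18 (adjusted p = 7.63e-17) and bchY at 4.97 ± 0.12. All 15 photosystem (median 4.37), 19 bacteriochlorophyll (median 2.34) and 7 carotenoid genes (median 2.58) were positive calls, also adjusted over the list alone. In the dark the photosystem genes lay a median of only 0.78 above the 5th percentile of all genes in the mutant, against 4.93 in wild type, so they had little room to fall. These lists had adjusted p = 2.33e-51, 1.19e-43 and 1.46e-16, or 3.63e-08, 6.61e-05 and 0.00555 with an estimated correlation. The change with light was lower in the mutant than in wild type for Dshi_1299 (-3.18 ± 0.35, adjusted p = 4.88e-07), napD (-2.77 ± 0.19), napA (-2.72 ± 0.18, adjusted p = 1.25e-10), Dshi_1411 (-2.65 ± 0.24) and uspA (-2.64 ± 0.23). Negative calls were made for 11 of 20 NADH dehydrogenase genes, 12 adjusted over the list alone (median -0.66, adjusted p = 1.23e-05, and 0.0187 with an estimated correlation), and for 8 of 17 TCA cycle genes, also adjusted over the list alone (median -0.64, adjusted p = 0.000261, and 0.00513 with an estimated correlation). So they were for 15 of 38 denitrification genes, also adjusted over the list alone (median -0.40, adjusted p = 1.26e-06, and 0.04 with an estimated correlation), and 9 of 21 genes of the cytochrome oxidase list, against 1 positive (10 and 2 adjusted over the list alone, median -0.38, adjusted p = 0.0142, and 0.0291 with an estimated correlation). Of 31 flagellum genes 21 were positive calls, 22 adjusted over the list alone (median 0.58, adjusted p = 5.33e-10, but adjusted p = 0.0501 with an estimated correlation). Leaving out clpX::Tn dark replicate 2 brought the medians of the cytochrome oxidase and denitrification lists to -0.58 and -0.24. Genes called in the planned fit numbered 1539, 113 positive and 1426 negative. Counting each probe once gave 723 (266 positive, 457 negative), and cyclic loess gave 528 (264 positive, 264 negative). Each probe counted once without clpX::Tn dark replicate 2 gave 1008 (404 positive, 604 negative).

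For blue light the interaction gave 6.15 ± 0.10 for pufB (adjusted p = 1.11e-21), 6.15 ± 0.17 for Dshi_2899, 5.66 ± 0.18 for pufA and 5.06 ± 0.12 for bchY. All 15 photosystem genes (median 4.30), 18 of 19 bacteriochlorophyll genes, 19 adjusted over the list alone (median 2.25), and all 7 carotenoid genes (median 2.50) were positive calls. Their lists had adjusted p = 7.98e-55, 3.89e-45 and 3.37e-17, or 2.11e-08, 5.27e-05 and 0.00615 with an estimated correlation. Negative values were those of Dshi_1299 (-4.62 ± 0.35, adjusted p = 9.18e-10), Dshi_1411 (-4.24 ± 0.24), uspA (-3.79 ± 0.23), ccoO (-3.62 ± 0.33, adjusted p = 2.18e-08), hemN (Dshi_0659, -3.62 ± 0.16) and napD (-3.36 ± 0.19). Negative calls were made for 13 of 38 denitrification genes, 14 adjusted over the list alone (median -0.48, adjusted p = 2e-08, and 0.0178 with an estimated correlation), and for 9 of 21 cytochrome oxidase genes against 1 positive (9 and 2 adjusted over the list alone, median -0.50, adjusted p = 0.00309, and 0.0128 with an estimated correlation). The same was found for 8 of 20 NADH dehydrogenase genes against 1 positive (12 and 1 adjusted over the list alone, median -0.46, adjusted p = 0.000387, and 0.0424 with an estimated correlation) and for 6 of 17 TCA cycle genes, 8 adjusted over the list alone (median -0.51, adjusted p = 0.00109, and 0.00886 with an estimated correlation). When clpX::Tn dark replicate 2 was left out, 15 NADH dehydrogenase and 11 TCA cycle genes were negative calls, with a denitrification median of -0.25. Genes called in the planned fit numbered 1301, 94 positive and 1207 negative. Counting each probe once gave 520 (203 positive, 317 negative), and cyclic loess gave 515 (244 positive, 271 negative). Each probe counted once without clpX::Tn dark replicate 2 gave 810 (348 positive, 462 negative).

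**Figure D3:**
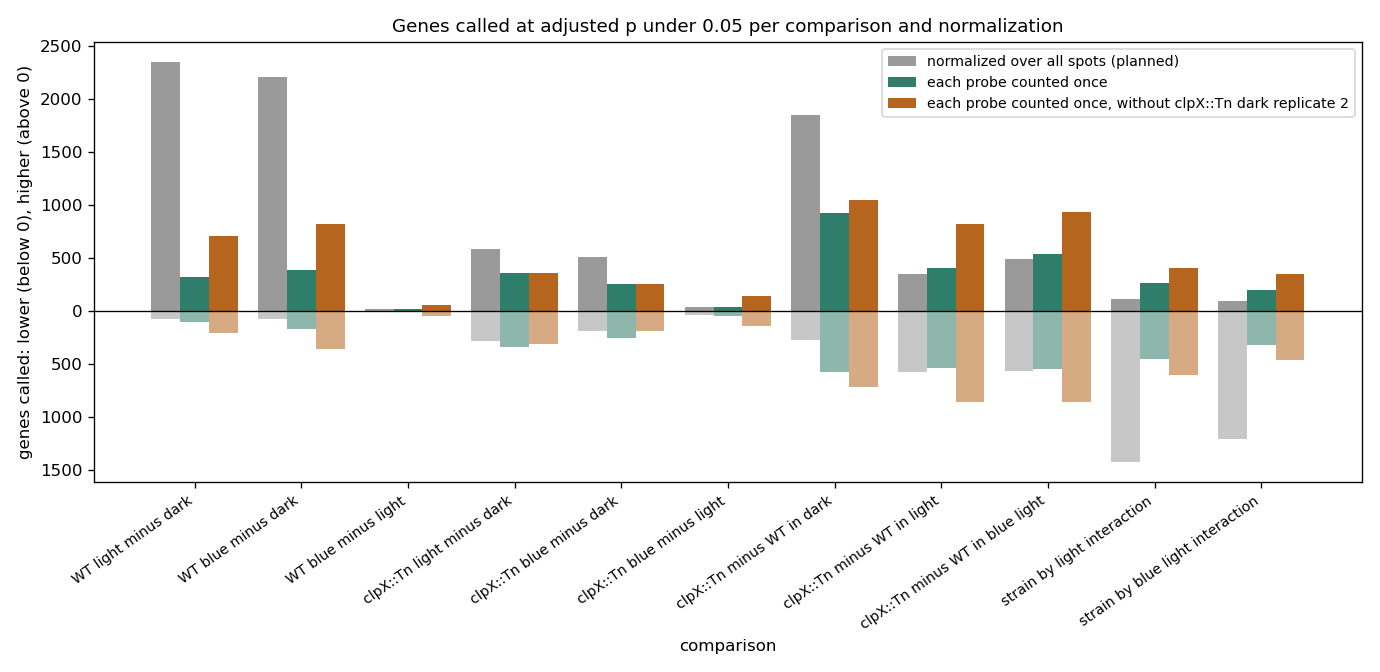
Number of genes called at an adjusted p under 0.05 (vertical axis, higher above 0 and lower below 0) in each of the 11 comparisons (horizontal axis) for 3 fits, shown by colour. Wild type light minus dark gave 2353 up and 71 down in the planned fit, and 325 up and 104 down with each probe counted once.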

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

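The splits of the arrays were planned, while the other tests of this part, and the fit that counts each probe once, were chosen after the results were seen. Gaps between arrays were examined in 72 groups of 4 arrays, 9 of which had 1 array far from the others, and chance alone gives about 1 in 20.

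The array labelled clpX::Tn dark replicate 2 stood apart from its group. Its mean correlation with the other 3 was 0.802, against 0.910 to 0.927 for them, and the probes spotted 10 times varied on it by a median CV of 32.8%, against 5.46% to 7.71%. Repeated spots of one probe share their RNA, so a CV of 32.8% is consistent with poor hybridization of this array, which may account for its distance. A label exchanged with another group would set it with that group in the genes that differ by over 1 on the log2 scale, but 78.6% to 85.0% of these were closer to its own group (65.9% or more at a difference of 0.5), and clpX lay in the range of the mutant, which argues against an exchange. A sample from outside the series stays open, and no biological explanation was tested.

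Photosystem genes fell in wild type in light and in blue light, and each light condition had its own slide. A slide difference of the size seen in wild type should have moved the same genes in the mutant on the same slides, where the medians were -0.70 in light and -0.85 in blue light against -5.03 and -5.04 in wild type. In the mutant in the dark these genes lay a median of only 0.78 above the 5th percentile of all genes. A fall of that size could therefore not be seen there. A slide effect that raised these genes on the dark slide should have raised them in the mutant as well. But only 68.5% of the photosystem probes in the mutant in light, and 76.8% in blue light, exceeded the limit set by the negative controls. Background could hide much of such a rise, so the mutant medians cannot decide between a slide effect and a response to light. A slide effect that took their signal down to background in light and blue light cannot be told apart from a response to light. Slide position went with strain.

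Most planned calls in wild type in light against dark were rises. The repeated spots carry 204 probes of 69 genes, and their weight in the normalization was tested by counting each probe once, which brought the median change of all genes from 0.342 to 0.0524. Median scaling, which has no quantile step but takes its median over the same spots, left 0.297, and -0.00737 with each probe counted once. Their weight is consistent with the shift, and a simulation in which only those 69 genes changed gave a median of 0.38 for the unchanged genes under the planned normalization and 0.08 with each probe once. A shift in the total amount of transcript stays open, since counting each probe once removes it as well.

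The test of the interaction itself called 1539 genes for light in the planned fit and 723 with each probe once, and 1301 and 520 for blue light. In the planned fit the median change of all genes was -0.27 in each interaction, and 1426 and 1207 of the calls were negative. These planned counts therefore include a shift of all genes that depends on the scaling. Cyclic loess called 528 and 515. In the dark, wild type replicate 2 had 74.97% of spots well above background against 78.0% to 78.4% for the other 3 arrays, and a median CV of repeated probes of 10.5% against 8.30% to 8.53%. The log2 value of ccoN was 12.47 on clpX::Tn dark replicate 1 against 11.01 to 11.08, within the range of the mutant in light. Dshi_1299 was at 10.187 on this array against 8.288 to 8.903, also within that range. Its pufA (10.806) and bchY (10.831) lay above the other mutant dark arrays, away from the light values. Mutant dark means of ccoN and Dshi_1299 therefore lean on this array, and the cause was not tested. Without it the planned counts were 1503 for mutant light minus dark and 1412 for blue minus dark. The log2 value of fliC was 8.32 on wild type dark replicate 3 against 8.22 on the others, and 11.14 on clpX::Tn light replicate 1 against 10.82 to 10.85. The log2 value of Dshi_1680 was 8.98 on wild type blue replicate 4 against 8.77 to 8.80, and 8.63 on wild type dark replicate 2 against 9.33 to 9.46.

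Other splits of the same 8 arrays were fitted for each pairwise comparison, 35 with the real one, and for each interaction 100 reassignments of the residuals, the real one included. In every case only 1, the real one, gave as many genes. With 35 splits, 1 of 35 is the lowest share that a pairwise comparison can reach. Splits that mix the groups also add the real difference to the spread, which can lower their counts. A slide or slide row difference would give the same outcome, and nothing is said about differences between cultures. In the planned fit the real count and the highest other were 2424 and 1 for wild type light minus dark, 2285 and 1 for blue minus dark, 22 and 3 for blue minus light, 870 and 69, 700 and 238, and 81 and 14 for the same contrasts in the mutant. They were 2122 and 938 for the strains in the dark, 933 and 82 in light, 1054 and 0 in blue light, and 1539 and 89, and 1301 and 305 for the interactions. With each probe once they were 429 and 0, 553 and 0, 20 and 3, 701 and 38, 510 and 250, 88 and 14, 1501 and 415, 946 and 82, 1083 and 0, 723 and 62, and 520 and 1 in the same order.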

How the results depend on the processing

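The fits that count each probe once or leave out clpX::Tn dark replicate 2 throughout were chosen after the results were seen, and the other alternatives were planned. Of 4136 values of 184 named gene results under the alternatives, 4040 kept their direction and side of the threshold, 74 lost their call, 22 gained one and 0 reversed. These genes, some of them not printed here, were mostly picked from the same data for their large, called changes. Few reversals were therefore built in, and the shares do not measure how stable other genes are. Low signal limits the precision of genes near the negative controls. Every count below is of called genes, and the counts not printed stayed within 1.5 times the planned ones. Where a count moved, the cause was not tested. By design, each gene's spread was estimated over all groups, so clpX::Tn dark replicate 2 also bears on comparisons outside its group. For gap (Dshi_1742) in wild type blue minus light, with each probe counted once, the change was 1.87 with and without that array. Its adjusted p was 0.0186 with the array and 7.82e-06 without it.

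With the processed intensity, mutant blue minus light gave 127 genes. Cyclic loess gave 375 for wild type light minus dark, 555 for wild type blue minus dark, 507 for mutant light minus dark, 204 for mutant blue minus dark, 1248 for the strains in the dark, and 528 and 515 for the light and blue light interactions. Median scaling gave 1423 and 1470 for wild type light and blue minus dark, 286, 134 and 33 for mutant light minus dark, blue minus dark and blue minus light, 1227, 573 and 700 for the strains in dark, light and blue light, and 674 and 503 for the interactions. The median over probes gave 13 for wild type blue minus light and 457 for mutant blue minus dark. Array weights, which weighted clpX::Tn dark replicate 2 at 0.0156, gave 3612 for wild type blue minus dark, 474 for wild type blue minus light, 1554 for mutant blue minus light, 2234 and 2368 for the strains in light and blue light, and 2337 and 2137 for the interactions. With only the arrays compared, mutant light minus dark, blue minus dark and blue minus light gave 38, 25 and 707, and the strains in dark, light and blue light gave 1306, 1413 and 2108.

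Leaving out 1 compared array at a time gave 9 to 33 for wild type blue minus light, 474 to 1503 for mutant light minus dark, 270 to 1412 for mutant blue minus dark and 45 to 67 for mutant blue minus light. It gave 2150 to 2279 for wild type light minus dark, 2025 to 2103 for wild type blue minus dark, 1906 to 2602, 796 to 871 and 914 to 974 for the strains in dark, light and blue light, and 1372 to 2073 and 1140 to 1856 for the interactions. Without clpX::Tn dark replicate 2, outside the comparison, wild type blue minus light gave 108, mutant blue minus light 277, and the strains in light and blue light 1668 and 1781. Each probe counted once gave 429 and 553 for wild type light and blue minus dark and 723 and 520 for the interactions. Without that array as well it gave 922, 1175 and 105 for the wild type contrasts, 444 and 286 for mutant blue minus dark and blue minus light, 1677 and 1797 for the strains in light and blue light, and 1008 and 810 for the interactions.

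Of the 42 lists in 11 comparisons, camera called 96 in the planned fit, 61 with an estimated correlation, 105 with each probe once, and fry called 288. Replicate numbers followed the slide column. With the replicate number as a block no count moved over 1.5 times. Of 60 pairs of arrays with one number, 19 had a correlation over 0.1 after group means were removed (-0.465 to 0.359, median 0.07). The median was -0.015 for pairs with different numbers. Of 24 arrays, 12 were closest to their own number, more than an even spread over the numbers gives. A shared structure by number or slide column therefore stays open. The numbers were not taken to pair samples, because nothing in the labels says what they mark. A slide term was not run, since slide and light coincide.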

Other observations

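The tests of explanations in this part were chosen after the results were seen, and the lists were fixed beforehand. Values are from the fit that counts each probe once. Against wild type, 8 of 19 genes for SOS response, repair and competence were higher in the mutant in the dark and 7 of 19 in blue light, with 1 lower in each, but the list did not pass camera in these conditions. The comF and dprA genes rose by 1.18 ± 0.08 and 1.27 ± 0.11 in the dark. Of 76 transposase and integrase genes 15 rose and 2 fell in light (median 0.12, adjusted p = 0.00504, and 0.00402 with an estimated correlation), and 21 rose and 1 fell in blue light (median 0.14, adjusted p = 0.00524, and 0.0048 with an estimated correlation). Of 13 heme biosynthesis genes 5 fell and 1 rose in each condition, with adjusted p = 0.0135, 0.00916 and 0.00843 in dark, light and blue light and 0.0353, 0.027 and 0.0297 with an estimated correlation. In the dark the median of that list was -0.16, but 0.08 in the planned fit, and without clpX::Tn dark replicate 2 the p-values with an estimated correlation were 0.0527, 0.0875 and 0.0737, and in light the list had adjusted p = 0.0505. Transposase and integrase genes numbered 27 up and 4 down in light without that array. Of 11 sigma factor genes 5 were positive and 1 was a negative call in the light interaction (median 0.60, adjusted p = 0.0405, but adjusted p = 0.0641 with an estimated correlation, and a median of 0.12 and adjusted p = 0.0581 without that array). The phage tail gene Dshi_2465 was lower in all 3 conditions, by -1.79 ± 0.15 in the dark, -1.60 ± 0.15 in light and -1.77 ± 0.15 in blue light.

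A run of 11 neighbouring genes from pedF (Dshi_2663) to Dshi_2673, which hold cytochrome c, pyrroloquinoline quinone and ABC transporter products, had 10 genes lower in the mutant in each condition, with medians of -1.15 in the dark, -1.83 in light and -1.65 in blue light. The 6 genes from Dshi_1675 to Dshi_1680 had 5 genes lower in light than in the dark in the mutant (median -2.26) and 5 higher in blue light than in light (median 2.02). In wild type 0 of them were called in light minus dark (median -0.26), and the light interaction called 5 of them (median -1.85). Both runs were picked after their values were seen. On plasmid pDSHI02 42, 44 and 48 of 125 genes were lower in the mutant in dark, light and blue light and 4, 3 and 2 higher (medians -0.15, -0.18 and -0.25), with adjusted p = 0.000129, 3.18e-07 and 5.02e-09, but adjusted p = 0.193, 0.0894 and 0.0575 with an estimated correlation, and in the dark the median was 0.09 with median scaling. Without clpX::Tn dark replicate 2, 61, 59 and 68 of them were lower, and the values with an estimated correlation were 0.000118, 0.000666 and 0.000156.

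Replicons differed in the share of genes below 0 in mutant minus wild type. On pDSHI05 it was 84.3% of 70 genes in the dark, 91.4% in light and 95.7% in blue light, and on pDSHI02 68%, 80% and 88%. On the chromosome it was 43.8%, 48.4% and 48.6%, and on pDSHI04 17.0%, 3.77% and 7.55%. No explanation was tested, and DNA was not measured.

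Hypothesis: the rise of nap genes in wild type in light was part of a rise of the whole denitrification pathway. Only 11.1% of the 18 nir, nor and nos genes were called up. Their log2 changes were -0.22 to 0.56 (median 0.11), against 1.26 to 2.51 (median 1.44) for the 7 nap genes. This argues against a rise of the later steps as large as that of nap. Smaller rises stay open, because the calls depend on the spread. Without clpX::Tn dark replicate 2, 16 of 38 denitrification genes were called up, and the share of nir, nor and nos genes was not counted there.

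Hypothesis: the genes called between the strains in light and in blue light were unrelated. In both, 736 genes were called with the same direction, against 126 for independent lists. The test decides little, because both comparisons set the same mutant against the same wild type. They share no arrays, but they share the normalization and the estimate of each gene's spread. Both slides also set the strains on the same slide rows.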
